A study of Mus musculus with 8 samples.

How the data were processed

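The measurements were genome-wide expression levels in the hearts of 8 male mice, given in the labels as strain CH3, aged 8 to 10 weeks and weighing 25 to 30 g. Each mouse received either phosphate-buffered saline (placebo) or DJ-1 protein 1 hour before the left anterior descending coronary artery was tied for 45 minutes, and the artery was then reopened for 2 hours. Total RNA with an RNA integrity number above 7 was extracted from myocardial tissue, and 100 ng of it was amplified, labelled with biotin and hybridised to Affymetrix whole-transcript arrays, per the labels' protocols. The labels gave 4 arrays to the placebo group and 4 to the DJ-1 group, and every array carried a replicate number from 1 to 4.

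The deposited table holds log2 expression values of 35556 probe sets on the 8 arrays, made by the authors with the robust multi-array average (RMA), per the submitters' processing notes. RMA as usually run corrects the background, applies quantile normalization to the probes of all arrays and summarises them into probe sets. Its version, the software used and the annotation build are not given in the sources used here. Median array values lay between 5.25 and 5.35, as log2 values of this kind do, and no further normalization was applied for the main results. No scan date or slide was used here, so hybridisation batches were not examined. The sample codes in the labels run consecutively through the placebo samples and then through the DJ-1 samples, so if they follow an order of processing, batch and treatment cannot be told apart in any group difference. Correlations between arrays ran from 0.978 to 0.987, and no pair of arrays held identical values (0 pairs). The number of arrays limits the precision of each difference: the median standard error was 0.117 on the log2 scale and the median 95% confidence interval extended 0.256 to each side.

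Gene names came from the platform annotation. A single gene symbol was given for 21789 probe sets, several for 1621 and none for 12146, and no gene was named from a probe set with several. The Entrez identifier of 21698 of the singly named probe sets was found in the RefSeq gene table used here, which changed 0 of their symbols. Where a gene had more than 1 probe set (999 genes), the probe set with the highest mean over all 8 arrays was taken, which gave 19938 genes. Olfactory receptor genes, which heart muscle hardly transcribes, served as a guide to the background level: 1027 of them had a median of 3.26 and a 95th percentile of 4.74 on the log2 scale, and 13693 genes lay above that percentile.

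DJ-1 was compared with placebo by limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the 19938 genes and no covariate. The p-values of this fit for single genes measure the spread between these samples. The labels number the samples within each group, and they were taken here as tissue of separate mice. Differences are given as DJ-1 minus placebo on the log2 scale, with the standard error (SE) or 95% confidence interval of the fit, and group means with their SD over 4 arrays. The genes named were fixed by rule before the data were examined: Park7; up to 12 genes per direction past adjusted p 0.05 without overlap between the groups; where fewer passed, the genes of smallest p under 0.01 without overlap and with a mean level above the median of all genes (5.79), described as not passing; and the 3 members of smallest p in each gene list, with further members past adjusted p 0.05 over the list alone. Olfactory and vomeronasal receptor, predicted and small RNA genes counted in the totals but were not named by this rule.

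A set of 30 gene lists with 509 entries was written before the data were examined, and 463 entries were measured under a single symbol. Some entries were matched through an older symbol: Ddx58 for Rigi, Arntl for Bmal1, Atp5a1 for Atp5f1a, Atp5b for Atp5f1b, Atp5c1 for Atp5f1c and Atp5o for Atp5po. The lists cover pathways (immediate early genes; acute cytokines, chemokines and NF-kappaB targets; interferon-stimulated genes; NRF2 targets; antioxidant enzymes and metallothioneins; methylglyoxal handling and the receptor for advanced glycation end products; heat shock proteins; the unfolded protein and integrated stress response; hypoxia and glycolysis; oxidative phosphorylation; fatty acid oxidation and PPAR targets; apoptosis; autophagy; extracellular matrix; circadian clock; cell cycle). They also cover markers of cell types that heart tissue, blood or neighbouring tissue could contribute (neutrophils, monocytes and macrophages, lymphocytes, ventricular and atrial cardiomyocytes, fibroblasts, endothelium, smooth muscle and pericytes, erythroid cells, adipocytes, skeletal muscle, lung epithelium, mesothelium, platelets). Each list was tested against all other genes with camera from limma at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists. At this setting camera compares genes with genes and treats them as nearly independent, so its p-values do not measure the spread between hearts. The arrays' list means (each gene relative to its mean over the 8 arrays) were also compared by an exact two-sided permutation test over the 70 assignments of the arrays, whose smallest possible p is 0.029.

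The fit was checked on simulated arrays with the real genes' means and moderated spreads. The noise was independent for each gene and array, and 200 genes were changed at once. Of 50 genes changed by 0.5 on the log2 scale, 52% were recovered at adjusted p 0.05 in the simulated comparison of DJ-1 with placebo over 19938 genes. All of those changed by 1, 1.5 or 2 (100% of 50 each) were recovered, with 12 false calls, and no gene was called (0 genes) when nothing was changed. In the simulated list test, with independent genes, a list shifted by 0.7 was called and 0 lists were called without a shift.

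The alternatives fixed beforehand were the replicate number as a block, each array left out in turn, quantile normalization, centring each array on its median, filters on dim genes, the mean of all probe sets of a gene, all probe sets, an intensity trend with robust estimation, array weights, a test without moderated variances, camera with an estimated correlation, camera on ranks and fry. Cyclic loess, leaving out DJ-1 replicates 3 and 4 together, a filter at the olfactory receptors' 95th percentile and the exact permutation test of the list means were added after the data had been seen. Figures and tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Probe sets with no symbol or several (13767) entered only the alternative that tested all probe sets, and no genomic positions are given because the array's genome build is not given in the sources used here.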

Results

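Expression profiles were obtained from myocardial tissue of 8 mice after coronary occlusion for 45 minutes and reperfusion for 2 hours. Before ligation, 4 mice had received DJ-1 protein and 4 had received saline as placebo. DJ-1 is a small redox-sensitive protein encoded by Park7, and its loss causes a familial form of Parkinson disease. The comparison asked which transcripts differed in reperfused myocardium when DJ-1 had been given 1 hour before ischaemia. The deposited values cover 35556 probe sets, of which 19938 genes with a single symbol were tested. The array medians were 5.25, 5.28, 5.29 and 5.26 in placebo replicates 1 to 4 and 5.28, 5.28, 5.34 and 5.35 in DJ-1 replicates 1 to 4. The median correlation between arrays was 0.984 within groups and 0.984 between groups.

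The Park7 transcript itself stood at 11.03 ± 0.15 (SD, n = 4) in placebo hearts and 11.02 ± 0.16 (SD, n = 4) in DJ-1 hearts. The difference of -0.01 (SE 0.11, 95% confidence interval -0.25 to 0.23) was smaller than the spread between replicates. The mice had received the protein, so this transcript reports the endogenous gene and does not measure the treatment.

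No single gene (0 of 19938) passed an adjusted p of 0.05 in the limma comparison of DJ-1 with placebo hearts. The genes of smallest p with higher levels in all 4 DJ-1 hearts included Pdk4, the kinase that inhibits pyruvate dehydrogenase, at 12.02 ± 0.21 (SD, n = 4) in placebo and 12.56 ± 0.10 (SD, n = 4) in DJ-1 hearts. They also included Nt5e, the cell-surface enzyme that makes adenosine from AMP, with a difference of 0.54 (SE 0.11). The zinc-binding metallothionein Mt1 was at 11.06 ± 0.12 in placebo and 11.54 ± 0.14 in DJ-1 hearts (SD, n = 4 each). Among the genes of smallest p with lower levels in all 4 DJ-1 hearts were the apelin receptor Aplnr, with a difference of -0.63 (SE 0.15), and Lta4h, a leukotriene A4 hydrolase, with -0.36 (SE 0.08). Each of these 5 genes had an adjusted p of 0.824, so none of them passed.

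The other 9 genes named on the higher side differed by 0.34 to 0.73. Gprc5a, an orphan G protein-coupled receptor, differed by 0.73 (95% confidence interval 0.34 to 1.11). Slc4a1, the anion exchanger of red blood cells, differed by 0.59 (0.25 to 0.93). Ugdh, which makes UDP-glucuronate, differed by 0.56 (0.26 to 0.86). The transcriptional coregulator Cited2 differed by 0.35 (0.15 to 0.56), and the tubulin gene Tubb6 by 0.37. The differences of Mbd1, which binds methylated DNA, Ifitm5, Gpr31b and Ttyh1 were 0.48, 0.42, 0.40 and 0.34. The other 10 genes named on the lower side differed by -0.61 to -0.34. Klhl4 had a difference of -0.61 (-0.89 to -0.32), and Prox1, a transcription factor of lymphatic endothelium that cardiomyocytes also express, had -0.52 (-0.83 to -0.21). The endothelial gene Myct1 had -0.49 (-0.72 to -0.25), the matricellular gene Thbs2 -0.44 (-0.68 to -0.21), and the junctional adhesion gene Jam3 -0.37 (-0.56 to -0.18).

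The desaturase gene Scd2 differed by -0.48, and the coactivator gene Ppargc1b, which acts on mitochondrial genes, by -0.34. Septin4, Ebf1 and Ncdn differed by -0.39, -0.35 and -0.34. All 24 of these genes had an adjusted p of 0.824. They were taken from 19 genes on the higher and 34 on the lower side that met the same rule. Adjusted over the list alone, 3 members of the 30 fixed lists passed 0.05, against 0 over all genes tested: Pdk4 (0.011), Mt1 (0.0113) and Slc4a1 (0.0169). This adjustment takes each list by itself and makes no correction over the 30 lists, so some passes can arise by chance.

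**Figure D1:**
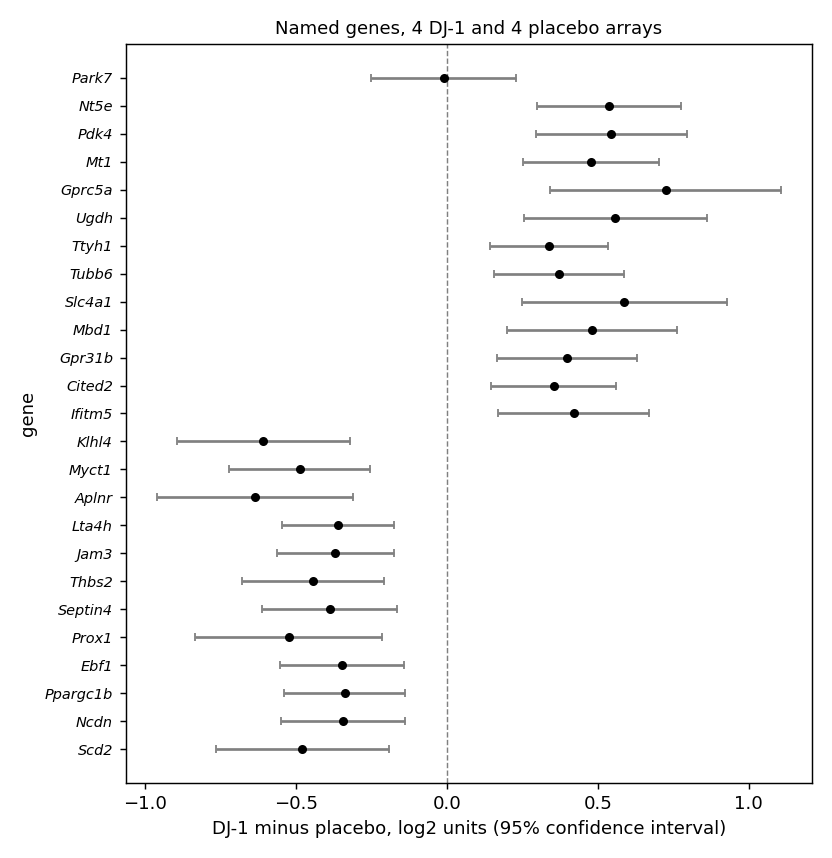
Log2 difference between DJ-1 and placebo hearts (x axis, DJ-1 minus placebo, log2 units) of Park7 and the 24 named genes (y axis). Points are the differences of the limma fit over 4 DJ-1 and 4 placebo arrays, and bars are their 95% confidence intervals. The interval of Park7 runs from -0.25 to 0.23, and the intervals of the other genes, which were chosen for small p, lie on 1 side of 0 although none passed adjustment.

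Across all genes, 217 had an unadjusted p under 0.01 in the limma fit, against 199 given by chance, and 1194 had an unadjusted p under 0.05, against 997 by chance. A test without moderated variances also called 0 genes, with 1118 at an unadjusted p under 0.05. The smallest adjusted p values were 0.105 for Pramel27, with a difference of 0.92 at a mean level of 4.23 (within the range of the olfactory receptors), and 0.261 for a predicted transcript. Levels in the DJ-1 and placebo arrays did not overlap for 642 genes (3.22%), where chance gives 2.86%. Of the 217 genes, 151 were higher and 66 lower in DJ-1 hearts, but this split depended on the scaling: 108 were higher and 84 lower with quantile normalization, 89 higher and 129 lower with each array centred on its median, and 106 higher and 91 lower with cyclic loess. The simulated comparison, with independent noise and 200 genes changed at once, recovered all of the genes changed by 1 and 52% of those changed by 0.5. It holds none of the differences that whole arrays share in the real data, so it does not give the power here. In the real data 8 genes differed by at least 1, and none of them passed.

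Markers of neutrophils, the white blood cells that enter reperfused myocardium early, had a higher mean in DJ-1 hearts, with a mean shift of 0.68 over 15 genes. All 15 had a higher mean, led by Lcn2 with 1.07 (SE 0.49), the collagenase gene Mmp8 with 1.25 (SE 0.68) and the granule protein gene Ngp with 1.06 (SE 0.57), and 1 of the 15 had an unadjusted p under 0.05. Acute cytokines, chemokines and NF-kappaB targets had a mean shift of 0.32, and all 26 measured members had a higher mean. Oncostatin M (Osm) differed by 0.57 (SE 0.32), its feedback inhibitor Socs3 by 0.53 (SE 0.30) and the neutrophil chemokine Cxcl2 by 0.57 (SE 0.35). With each array left out these differences ran from 0.25 to 0.83 for Osm, 0.33 to 0.78 for Socs3 and 0.15 to 0.88 for Cxcl2, the lowest for Osm and Cxcl2 without DJ-1 replicate 2. Both lists passed camera with the preset correlation (adjusted p = 0.00313 for neutrophils and 0.00295 for cytokines). Neither passed with an estimated correlation (adjusted p = 0.821 for each), and the exact permutation p of the array means was 0.343 for neutrophils and 0.4 for cytokines. The spread between hearts was wide: the neutrophil list means were -0.19, 0.89, -0.55 and -1.50 in placebo replicates 1 to 4 and 0.84, 1.20, -0.14 and -0.54 in DJ-1 replicates 1 to 4. Without placebo replicate 4 the shifts were 0.29 for neutrophils (adjusted p = 0.449) and 0.17 for cytokines (adjusted p = 0.191), and without DJ-1 replicate 2 they were 0.39 (adjusted p = 0.349) and 0.08 (adjusted p = 0.814). The neutrophil shift was 0.51 without DJ-1 replicate 1 (adjusted p = 0.0897), 1.09 without placebo replicate 2 and 1.36 without DJ-1 replicates 3 and 4. The cytokine shift was 0.55 without DJ-1 replicate 3 and 0.65 without DJ-1 replicates 3 and 4. Leaving out those 2 arrays keeps placebo replicates 3 and 4, where the neutrophil means were lowest in that group. The neutrophil means of replicates 1 and 2 alone were -0.19 and 0.89 in placebo and 0.84 and 1.20 in DJ-1 hearts.

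**Figure D2:**
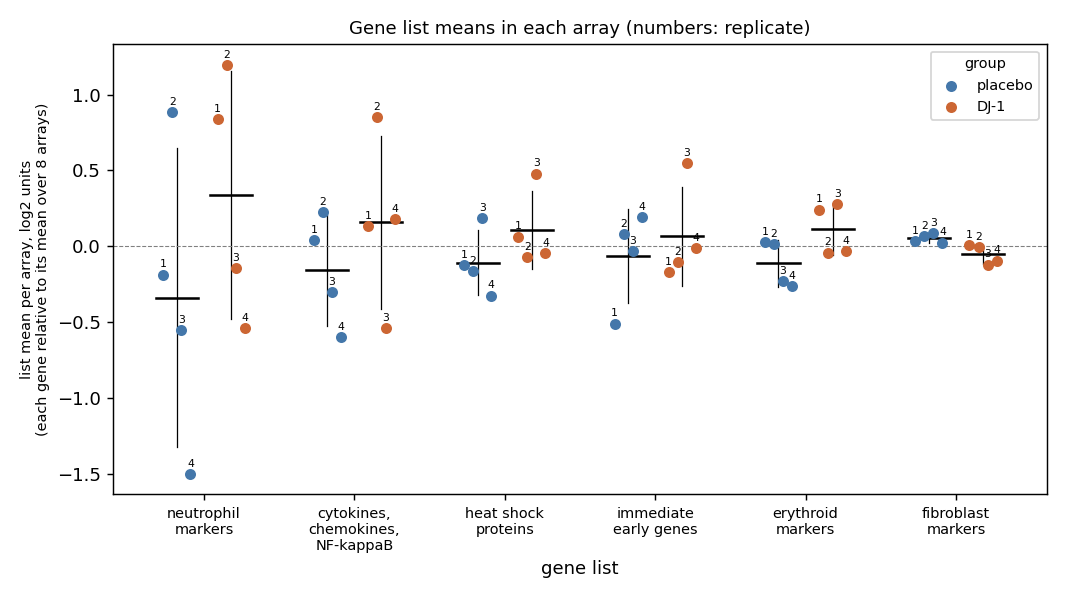
Mean of 6 gene lists in each array (y axis, log2 units, each gene relative to its mean over the 8 arrays), for placebo and DJ-1 hearts. Points are arrays with their replicate numbers, horizontal lines are group means and vertical lines are SD over 4 arrays. The neutrophil means spread from -1.50 to 1.20 and the groups overlap, while the fibroblast means of the 4 DJ-1 arrays all lie below those of the 4 placebo arrays.

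Fibroblast markers had a lower mean in DJ-1 hearts, with a mean shift of -0.11 over 12 genes, 10 of which had a lower mean. Gelsolin (Gsn) was at 10.14 ± 0.02 in placebo and 9.93 ± 0.07 in DJ-1 hearts (SD, n = 4 each), the proteoglycan gene Lum differed by -0.31 (SE 0.13) and the receptor gene Pdgfra by -0.25 (SE 0.14). The list passed camera with the preset correlation (adjusted p = 0.0191) and not with an estimated correlation (adjusted p = 0.821). Every DJ-1 array had a lower list mean than every placebo array, which gives the smallest p that exact permutation allows here (p = 0.0286), or 0.857 after adjustment over the 30 lists, which no single list could pass in this design. The lowest means, -0.12 and -0.09, were those of DJ-1 replicates 3 and 4, the arrays that also stood apart on the first principal component, at 19.6 and 23.5 against -15 to 5.3 for the other arrays. Without these arrays, a setting that keeps placebo replicates 3 and 4, the shift was -0.05 (adjusted p = 0.238). With cyclic loess it was -0.08 (adjusted p = 0.0809), and among genes above the median level it was -0.11 (adjusted p = 0.0502). Without placebo replicate 2, placebo replicate 3 or DJ-1 replicate 3, adjusted p was 0.0704, 0.0753 or 0.0837. Smooth muscle and pericyte markers had a mean shift of -0.09 and did not pass (adjusted p = 0.0531). They passed without placebo replicate 1 (-0.12, adjusted p = 0.0197), without DJ-1 replicate 3 (-0.13, adjusted p = 0.0172) and with an intensity trend (adjusted p = 0.0368), and not with an estimated correlation (adjusted p = 0.821). Their leading members were Kcnj8 with -0.44 (SE 0.13), Pdgfrb with -0.30 (SE 0.12) and Notch3 with -0.20 (SE 0.10).

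Heat shock proteins and co-chaperones had a mean shift of 0.21, with 14 of 16 members higher, and did not pass (adjusted p = 0.0531). Their leading members were Hspa1a, an inducible chaperone gene, with 1.11 (SE 0.50), Hspb1 with 0.41 (SE 0.19) and Dnaja1 with 0.42 (SE 0.22). Hspa1a ranged from 7.89 to 10.12 among placebo arrays and from 8.76 to 10.85 among DJ-1 arrays. The list passed with quantile normalization (adjusted p = 0.022), cyclic loess (adjusted p = 0.021) and each array centred on its median (adjusted p = 0.0251), and its shift was 0.09 without DJ-1 replicate 3 (adjusted p = 0.613). Over the camera alternatives on expression values its adjusted p ran from 0.000352 among genes above the median level to 0.821 with an estimated correlation. The unfolded protein and integrated stress response had a mean shift of 0.12 (adjusted p = 0.0823), with 15 of 18 members higher. Asparagine synthetase (Asns) differed by 0.39 (SE 0.17), Creld2 by 0.28 (SE 0.18) and Trib3 by 0.18 (SE 0.11). This list passed with quantile normalization (adjusted p = 0.022) and cyclic loess (adjusted p = 0.0138), without placebo replicate 3 (0.18, adjusted p = 0.00965) and without DJ-1 replicate 4 (0.17, adjusted p = 0.000423), and not with an estimated correlation (adjusted p = 0.821). The shift was 0.07 without DJ-1 replicate 3 (adjusted p = 0.449) and 0.07 without placebo replicate 4 (adjusted p = 0.394). Immediate early genes had a mean shift of 0.13 (adjusted p = 0.275), with Fosl2 at 0.38, Nr4a3 at 0.53 and Atf3 at 0.48. The mean shift was -0.03 without DJ-1 replicate 3, and the list passed among genes above the median level (adjusted p = 0.00394) but not with an estimated correlation (adjusted p = 0.821).

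Among metabolic and redox genes, no list passed with all genes and all 8 arrays. Fatty acid oxidation and PPAR targets had a mean shift of 0.10 (adjusted p = 0.198), led by Pdk4, Txnip with 0.35 (SE 0.17) and Ppargc1a with 0.26 (SE 0.15). This list passed without DJ-1 replicates 3 and 4 (0.17, adjusted p = 0.0103), a setting that keeps placebo replicates 3 and 4. It also passed among genes above the median level (adjusted p = 0.00394), and not with an estimated correlation (adjusted p = 0.821). Antioxidant enzymes and metallothioneins had 0.07 (adjusted p = 0.385), led by Mt1, Mt2 with 0.64 (SE 0.21) and Glrx with 0.16 (SE 0.10), and passed among genes above the median level (adjusted p = 0.0137) but not with an estimated correlation (adjusted p = 0.821). NRF2 targets, the genes induced by the oxidant-sensing factor often set in relation to DJ-1, had a mean shift of 0.06 with 11 of 21 members higher, although camera ranked the list in the opposite direction (adjusted p = 0.91). The shift was between 0.01 without DJ-1 replicate 1 and 0.12 without placebo replicate 1 when each array was left out, and 0.21 without DJ-1 replicates 3 and 4 (adjusted p = 0.0954). In both groups the NRF2 list mean was above 0 in replicates 1 and 2 and below 0 in replicates 3 and 4. The value of 0.21 comes from a setting that keeps placebo replicates 3 and 4, so it does not show the treatment alone. The leading members were Osgin1 with 0.23, Me1 with -0.17 and Abcc1 with -0.20. The list of methylglyoxal handling, to which DJ-1 belongs as a proposed deglycase, had a mean shift of 0.01 and a median of -0.01, with a camera rank on the lower side (adjusted p = 0.981), and its leading members were Esd at -0.18, Hmgb1 at 0.27 and Ager at 0.19. Hypoxia and glycolysis had -0.02 (adjusted p = 0.515), with Hif1a at -0.23, Ddit4 at 0.36 and Hk2 at -0.15. Nuclear-encoded oxidative phosphorylation had -0.01 (adjusted p = 0.579), with Ndufb8 at -0.19, Cox7a1 at -0.07 and Sdhd at 0.08.

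The remaining pathway lists did not pass with all 8 arrays. Apoptosis regulators had a mean shift of 0.10 (adjusted p = 0.385), with the death receptor Fas at 0.50, Tnfrsf12a at 0.44 and the survival gene Bcl2l1 at 0.24. Their median was 0.01, with 7 members higher and 7 lower. Extracellular matrix and remodelling genes had a mean shift of 0.06 (adjusted p = 0.786), while their median was -0.02. The matricellular gene Thbs1 was higher in all 4 DJ-1 hearts, at 9.78 ± 0.30 in placebo and 10.37 ± 0.32 in DJ-1 hearts (SD, n = 4 each, adjusted p = 0.824), and the differences of Timp3 and Tgfb2 were 0.29 and -0.17. Circadian clock genes had -0.06 (adjusted p = 0.385), with Nfil3 at 0.53, Bhlhe41 at -0.34 and Per3 at -0.36. Interferon-stimulated genes had 0.06 (adjusted p = 0.593), with Cxcl10 at 0.58, Rsad2 at 0.43 and Ifih1 at -0.21. Their shift was 0.14 without DJ-1 replicate 4 (adjusted p = 0.038) and 0.005 without DJ-1 replicate 1 (adjusted p = 0.707). It was 0.22 without DJ-1 replicates 3 and 4 (adjusted p = 0.000935), a setting that keeps placebo replicates 3 and 4. The list did not pass with an estimated correlation (adjusted p = 0.897). Autophagy genes had -0.02 (adjusted p = 0.4), with Tfeb at -0.15, Map1lc3b at 0.17 and Pink1 at -0.13. Cell cycle genes had -0.04 (adjusted p = 0.385), with Top2a at -0.29, Plk1 at -0.21 and Birc5 at 0.21.

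Other markers of the heart's own cells did not pass with all 8 arrays. Ventricular cardiomyocyte markers had a mean shift of -0.05 (adjusted p = 0.275), with titin (Ttn) at -0.31, Myh7 at -0.25 and Ryr2 at -0.18. Atrial markers had 0.06 (adjusted p = 0.786), with Bmp10 at 0.28, Nppa at 0.23 and Stard10 at -0.14. Endothelial markers had -0.04 (adjusted p = 0.385), led by the VEGF receptor gene Kdr with -0.48 (SE 0.16), Emcn with -0.21 and Tie1 with -0.13. Among blood cells, erythroid markers had 0.23 (adjusted p = 0.144), led by Slc4a1, Alas2 with 0.56 and Hemgn with 0.08, and the shift was 0.27 without DJ-1 replicate 4 (adjusted p = 0.028), while with all arrays adjusted p = 0.821 with an estimated correlation. Monocyte and macrophage markers had 0.01 (adjusted p = 0.955, median -0.04), with Lyve1 at 0.36, Fcgr1 at 0.22 and Ccr2 at 0.16. The shift was 0.14 without DJ-1 replicates 3 and 4 (adjusted p = 0.0294), a setting that keeps placebo replicates 3 and 4. With all arrays the adjusted p of this list was 0.987 with an estimated correlation. Lymphocyte markers had -0.03 (adjusted p = 0.796, median 0.02), with Cd79a at -0.44, Ms4a1 at -0.28 and Ighm at 0.21. Platelet markers had 0.06 (adjusted p = 0.593), with Gp5 at 0.20, Treml1 at 0.08 and Itga2b at -0.07.

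Markers of neighbouring tissues did not pass with all 8 arrays. Adipocyte markers had a mean shift of -0.08 but a median of 0.10, with a camera rank on the higher side (adjusted p = 0.593). Their leading member Car3 stood at 7.02 and 7.10 in placebo replicates 1 and 2 and between 4.22 and 4.57 in the other 6 arrays, and Ucp1 and Plin1 differed by 0.20 and 0.16. Skeletal muscle markers had -0.06 (adjusted p = 0.593), with Atp2a1 at -0.31, Myh1 at -0.26 and Actn3 at 0.12. Without placebo replicate 1, whose list mean was 0.64, the shift turned to 0.15 and passed (adjusted p = 0.0197), while with all arrays adjusted p = 0.897 with an estimated correlation. Lung epithelium markers had 0.03 (adjusted p = 0.385), with Sftpd at 0.34, Sftpa1 at 0.23 and Scgb1a1 at -0.64, and the sign of this shift turned with each of the scalings tried. Mesothelial and epicardial markers had 0.10 (adjusted p = 0.295), with Upk1b at 0.19, Krt19 at 0.17 and Muc16 at 0.17.

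The arrays also differed in how their values depended on expression level. The first principal component held 26.3% of the variance (exact permutation p = 0.429 between groups) and the second 20.2% (exact permutation p = 0.0571), and the groups overlapped on both. At low levels the medians of DJ-1 replicates 3 and 4 lay up to 0.09 and 0.14 above the mean of the 8 arrays, and at upper levels they lay below it. Among genes at an unadjusted p under 0.01 in the limma fit, 127 were higher and 25 lower below the median level, against 24 higher and 41 lower above it. The olfactory receptor genes, taken as background, had a median difference of 0.07.

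**Figure D3:**
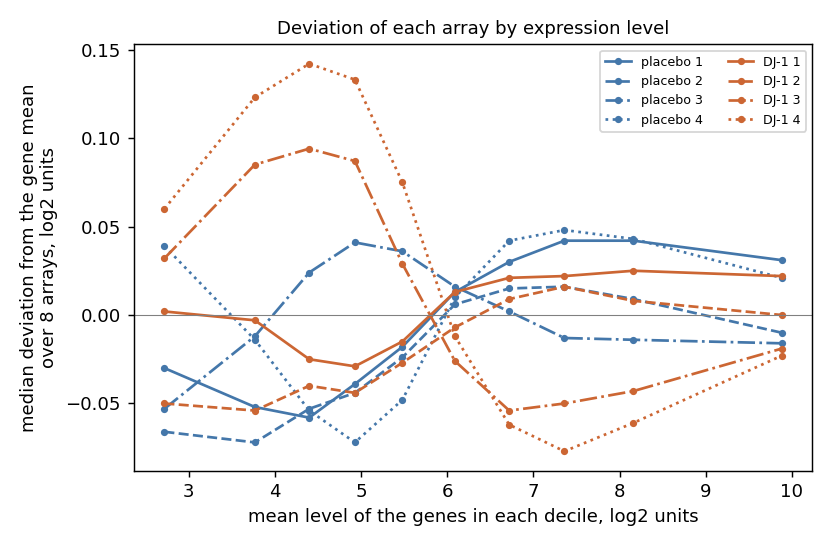
Median deviation of each array from the gene mean over the 8 arrays (y axis, log2 units) in 10 groups of genes ordered by mean level (x axis, log2 units). Each line is an array of the placebo or DJ-1 group. DJ-1 replicates 3 and 4 reach 0.09 and 0.14 at low levels and lie below 0 at upper levels.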

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

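The tests of the neutrophil pattern and the count of splits for genes past adjusted p 0.05 were chosen after the results they concern had been seen. Cyclic loess was added after the data had been seen.

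The skeletal muscle list mean of placebo replicate 1 was 0.64, far from the other placebo arrays (-0.25 to -0.10). In this array Myh1 was at 5.85 against 4.38 to 4.53 in the others. Cxcl2 was at 8.19 in placebo replicate 4 against 8.75 to 8.78, and Sftpa1 at 4.33 in the same array against 4.68 to 4.75. Ppargc1a was at 10.26 in placebo replicate 2 against 10.70 to 10.79. In the DJ-1 group, Septin4 was at 6.55 in replicate 3 against 6.81 to 6.86, and Me1 at 8.74 in that array against 8.81 to 8.83. Sftpd was at 4.0 in DJ-1 replicate 2 against 4.36 to 4.39, and Krt19 at 5.34 in DJ-1 replicate 1 against 4.96 to 5.01. Of 284 groups of 4 arrays examined, 9 held such a distant array, and chance gives 14.2.

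Splits of the 8 arrays into 4 and 4 did not exclude chance for the genes at an unadjusted p under 0.01 or for the gene lists. For genes past adjusted p 0.05 the splits decide nothing, because any split has at least the real count of 0 (35 of 35 splits), and another split gave up to 5. At least 217 genes at an unadjusted p under 0.01 were found in 9 of the 35 splits. The most, 589, came from replicates 1 and 2 of both groups against replicates 3 and 4 of both groups. This points to a structure of the arrays that divides the replicate numbers and does not follow the treatment. Its cause was not tested. At least 3 gene lists past adjusted p 0.05 were found in 32 of the 35, with up to 12 lists in another, so the list calls with the preset correlation do not exclude chance.

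The higher neutrophil mean in DJ-1 hearts may reflect differences between single hearts. The exact permutation p of the list means was 0.343, so differences between arrays that are unrelated to treatment could account for it. That permutation does not take up the division between replicates 1 and 2 and replicates 3 and 4. Each DJ-1 mean was above that of the same-numbered placebo array (0.84 and -0.19, 1.20 and 0.89, -0.14 and -0.55, -0.54 and -1.50). Whether the numbers pair mice is not known here. With the replicate number as a block, adjusted p was 6.78e-13 by camera with the preset correlation, which does not measure the spread between hearts. The array of placebo replicate 4 alone could also account for the call, since adjusted p was 0.449 without it, although 0.29 of the shift of 0.68 was left and the call likewise ended without DJ-1 replicate 1 or 2 (adjusted p 6.78e-13 to 0.821 over the camera alternatives on expression values). More blood left in the DJ-1 hearts cannot be told apart from the alternatives: Pearson's r of the erythroid and neutrophil list means over the 8 arrays was 0.53 (permutation p = 0.184), Spearman's rho was 0.476 (permutation p = 0.243), and 8 arrays leave this relation open, with r = 0.682 without the 2 arrays farthest from the erythroid median and r = 0.484 without the 2 farthest from the neutrophil median. An effect of DJ-1 on neutrophil entry remains an open explanation that these data do not separate from those.

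Of the genes at an unadjusted p under 0.01, 69.6% were higher in DJ-1 hearts. An intensity-dependent difference between arrays could account for this share, since 53.8% of such genes were higher after cyclic loess. Cyclic loess removes such a difference whatever its source, so the test cannot tell whether the normalization left it. Higher genes outnumbered lower ones only below the median level. No biological explanation was tested for this pattern.

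The lower fibroblast mean in DJ-1 hearts was tested against the same intensity-dependent difference. After cyclic loess the shift was -0.08 instead of -0.11 and the preset-correlation call ended (adjusted p = 0.0809), which met the bound set beforehand, so this difference may account for the call. It leaves most of the shift: the array means went from 0.05 ± 0.03 and -0.05 ± 0.06 (SD, placebo and DJ-1) to 0.04 ± 0.04 and -0.04 ± 0.03, the exact permutation p was 0.0286 before and after, and quantile normalization kept the call at -0.09 (adjusted p = 0.0451, and 0.00663 to 0.821 over the camera alternatives on expression values). A smaller share of fibroblasts would lower their matrix genes too, and the mean difference of Col1a1, Col1a2, Col3a1, Col5a1, Mmp2 and Lox was 0.004 (SE over the 6 genes 0.03), above the list by 0.11. That gap was not beyond the spread between arrays (exact permutation p = 0.2), so a smaller share and a change within fibroblasts cannot be told apart.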

How the results depend on the processing

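Cyclic loess, leaving out DJ-1 replicates 3 and 4 together, the filter at the olfactory receptors' 95th percentile and the exact permutation of list means were chosen after the data had been seen. In the alternatives tried, 0 genes passed adjusted p 0.05 in limma, except that 1 gene, Pramel27 (difference 1.01, adjusted p = 0.044), passed without DJ-1 replicate 3, so leaving out each array gave 0 to 1. At an unadjusted p under 0.01, 217 genes became 90 above the median level, 123 with a mean of at least 5, 136 above the olfactory percentile and 348 over all probe sets, since fewer or more features were tested, and 146 to 279 with each array left out. Of the values of the 112 genes named by rule, 1959 kept direction and side of the threshold and 12 reversed. The choice of genes largely set this outcome, so it says little about robustness. Genes named for no overlap between the groups cannot reverse when arrays are left out, others were named for small p, and none passed in the main fit. Of the list shifts, 476 kept both, 14 lost the threshold, 33 gained it and 37 reversed.

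With the preset correlation 3 lists passed. The number was 5 with quantile normalization, 7 among genes above the median level, 7 with a mean of at least 5, 6 with an intensity trend, 6 without DJ-1 replicates 3 and 4, 5 with camera on ranks, and 1 to 7 with each array left out (1 without placebo replicate 4 or DJ-1 replicate 2, 7 without DJ-1 replicate 4). It was 0 with an estimated correlation and 0 with fry. It was also 0 by exact permutation, where the smallest possible p cannot bring a single list past adjustment, so that count decides nothing. The lists gained were most often heat shock proteins and the unfolded protein response, and immediate early genes, fatty acid oxidation and antioxidant enzymes passed among genes above the median level. Replicate numbers did not pair single arrays: arrays with the same number correlated at 0.005, 0.171, 0.177 and 0.008, and among the DJ-1 arrays only replicate 2 correlated best with its own number. The numbers still carried a structure. DJ-1 replicates 1 and 2 correlated best with placebo replicate 2, and DJ-1 replicates 3 and 4 with placebo replicates 4 and 3. Splitting replicates 1 and 2 of both groups from replicates 3 and 4 gave 589 genes at an unadjusted p under 0.01. With the replicate number as a block, which takes up this division, 0 genes passed, 286 had an unadjusted p under 0.01 and 5 lists passed.

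Of the reversed values, only skeletal muscle markers without placebo replicate 1 (0.149, adjusted p = 0.0197) passed the threshold, and the cause was not tested. The lung list reached -0.004 with quantile normalization, -0.015 with median centring, -0.016 with cyclic loess and -0.059 without DJ-1 replicates 3 and 4. Median centring gave -0.035 for methylglyoxal handling and -0.029 for monocytes, and genes above the median level gave -0.018 and -0.017. Lymphocytes reached 0.032 with a mean of at least 5, and Park7 0.001 with array weights. Without DJ-1 replicates 3 and 4, Park7 reached 0.106, Atf3 -0.053, Ager -0.016, immediate early genes -0.073, hypoxia 0.006, oxidative phosphorylation 0.008 and autophagy 0.02. That setting keeps placebo replicates 3 and 4, so these values do not show the treatment alone.

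With each array left out, the ranges that crossed 0 were -0.023 to 0.235 for Actn3, -0.491 to 0.093 for Atp2a1, -0.399 to 0.093 for Myh1 and -0.082 to 0.042 for Park7. Among lists they were -0.155 to 0.022 for adipocytes, -0.024 to 0.228 for atrial markers, -0.04 to 0.001 for autophagy, -0.092 to 0.039 for cell cycle, -0.117 to 0.022 for clock genes and -0.055 to 0.034 for hypoxia. They were -0.031 to 0.217 for immediate early genes, -0.02 to 0.068 for lung, -0.085 to 0.013 for lymphocytes, 0 to 0.148 for mesothelium, -0.033 to 0.055 for methylglyoxal handling, -0.051 to 0.085 for monocytes, -0.001 to 0.17 for platelets and -0.148 to 0.149 for skeletal muscle. Shifts that kept their sign ranged from -0.083 (without placebo replicate 1) to -0.004 (without DJ-1 replicate 4) for endothelium, 0.014 (without placebo replicate 4) to 0.083 for extracellular matrix, -0.08 (without placebo replicate 2) to -0.023 (without placebo replicate 4) for ventricular markers and 0.042 (without DJ-1 replicate 1) to 0.109 (without DJ-1 replicate 3) for antioxidant enzymes. They ranged from 0.063 to 0.126 for apoptosis, -0.027 to -0.001 for oxidative phosphorylation, 0.068 to 0.128 for fatty acid oxidation, 0.169 to 0.276 for erythroid markers and -0.131 to -0.062 for smooth muscle and pericytes. Signal over background limits the dimmest genes: 108 of the 217 lay below the olfactory receptors' 95th percentile.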

Other observations

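The relations between list means were computed after the list results had been seen. The glucocorticoid test was planned before its mean was computed, although the difference of its gene Dusp1 had been seen. The difference of Per1, another of its genes, had been computed with the clock list.

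The neutrophil list tended to be high in the same hearts as the monocyte and cytokine lists, but none of the 6 relations tested passed adjustment. The neutrophil list had r = -0.231 with immediate early genes (exact permutation p = 0.599) and r = 0.118 with heat shock proteins (exact permutation p = 0.786). With 8 arrays these relations remain open. Over the 8 arrays the neutrophil mean and the monocyte and macrophage mean had a Pearson's r of 0.792 (exact permutation p = 0.0266, adjusted p = 0.0798 over 6 relations) and a Spearman's rho of 0.714 (exact permutation p = 0.0576, adjusted p = 0.173), with r = 0.80 without the 2 arrays farthest from the neutrophil median. The neutrophil mean and the cytokine mean had r = 0.784 (exact permutation p = 0.017, adjusted p = 0.0798) and rho = 0.762 (exact permutation p = 0.0368, adjusted p = 0.173), and r was 0.465 without those 2 arrays, so this relation rests partly on DJ-1 replicate 2 and placebo replicate 4. Heat shock proteins and immediate early genes had r = 0.46 (exact permutation p = 0.243, adjusted p = 0.364) and rho = 0.0238 (exact permutation p = 0.977, adjusted p = 0.977), with r = 0.166 without the 2 arrays farthest from the heat shock median. Both lists had their highest mean in DJ-1 replicate 3, at 0.48 and 0.55, where Hspa1a was at 10.85 and Nr4a3 at 9.35.

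In placebo replicate 1 the fast skeletal muscle gene Atp2a1 was at 6.99 against 5.24 to 5.64 in the other 7 arrays, and the airway gene Scgb1a1 was at 4.92 against 2.50 to 3.36. Other lung genes did not follow: Sftpd was at 3.84 in this array, its lowest level, and Sftpa1 was at 4.68 against 4.97 and 5.10 in DJ-1 replicates 3 and 4.

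Pdk4, Mt1, Mt2, Txnip and Nfil3, which were higher in DJ-1 hearts among the list members of smallest p, are all known to respond to glucocorticoids, and a glucocorticoid-type response in the DJ-1 hearts is a hypothesis that could link them. It was tested on 12 other glucocorticoid-induced genes (Fkbp5, Tsc22d3, Sgk1, Per1, Klf9, Zbtb16, Dusp1, Errfi1, Cebpd, Hif3a, Glul and Fam107a), of which Dusp1 and Per1 also belong to the immediate early and clock lists. All 12 had a higher mean in DJ-1 hearts, with a mean difference of 0.274, and the exact permutation p of the array means was 0.0571, so the test does not decide. The hypothesis also came from genes picked for their difference on these same arrays. Genes that vary together with them would tend to follow whatever the cause, so the test is not independent of that choice. Zbtb16 differed by 0.81, Fam107a by 0.70 and Fkbp5 by 0.48, while Klf9 differed by 0.01. The mean was 0.22 to 0.34 with each array left out and 0.295 after cyclic loess. The array means were -0.24, -0.07, 0.05 and -0.29 in placebo replicates 1 to 4 and 0.24, -0.05, 0.24 and 0.12 in DJ-1 replicates 1 to 4.

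Probe sets without a symbol or with several numbered 13767 of all those tested together, and 0 of them passed adjusted p 0.05 in limma (smallest 0.59). Of these, 118 were higher and 95 lower at an unadjusted p under 0.01.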
